A study of Sus scrofa with 9 samples.

How the data were processed

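RNA was measured in 9 libraries of porcine embryonic fibroblasts, with 3 libraries each at 0 h (control), 48 h and 72 h after insulin was added to the culture. Groups and replicate numbers were taken from the submitters' labels. Per the labels' protocols, ribosomal RNA was removed from total RNA and libraries were made with the NEBNext Ultra RNA kit, so transcripts without a poly(A) tail could also enter the libraries. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes may share reads. The concentration of insulin and the culture medium are not given in the sources used here either.

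The deposited values are FPKM (fragments scaled to the length of the gene and to the mapped fragments of the library), made by the authors, with 1 value per gene and library, per the file headers, and with 2 decimals. The submitters' processing notes name HISAT2 2.1.0, featureCounts 2.0.2, RSEM 1.2.28 and DESeq2 (no version), and the genome build Sscrofa11.1. They give no role or order, so which tool made the FPKM values and from which annotation is not given in the sources used here. FPKM values are scaled within each library. A few very abundant transcripts that rise therefore lower the values of all others, and a gene's value depends on the length assigned to it. Genes with near-identical copies, such as ribosomal protein genes and their processed pseudogenes, can share reads in ways that the deposited values no longer show, and their values are uncertain to that extent.

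Each file listed 30477 gene IDs, and 14864 of them were paired with a symbol. Genes with FPKM of at least 1 in at least 3 libraries were tested, which left 11063 genes, 9875 of them (89.3%) with a symbol. Coordinates, gene type and gene span, which includes introns and only stands in for transcript length, came from a RefSeq table of Sscrofa11.1 matched by symbol, for 9310 of the tested genes (84.2%). The insulin pathway genes SLC2A1, SLC2A3 and IGFBP3 were not matched by symbol and were not analysed here. Values of some other genes are not reported here.

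Values were taken as log2(FPKM + 1), with a pseudocount of 1, and a fold change is on that scale, which understates the change of low genes. All 9 libraries entered a single fit in limma 3.58.1 (R 4.3.3), with group as the only term and empirical Bayes moderation with a trend in the prior variance. The contrasts were 48 h against 0 h, 72 h against 0 h and 72 h against 48 h, each two-sided, with a moderated F-test over the 3 times. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Adjusted p values of single genes are from limma and adjusted over the 11063 genes, unless the text says that they were adjusted over a list alone.

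The 38 gene lists were fixed before the data were examined, along with the tests, the settings to be varied and the rule for naming genes. They cover insulin signalling and its target genes, metabolism, the cell cycle, ribosomes, matrix and fibroblast state, stress and inflammatory responses, and markers of other cell types that a fibroblast culture could hold. The 35 lists with at least 5 tested members entered limma's camera test, which compares a list with the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. It was repeated with an estimated correlation. Per-list counts were given at the adjusted p over all genes and over the list alone. The fry test, which asks whether the genes of a list move on balance one way or in either direction, was run as an alternative.

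Genes were named by rule. Part a took the 6 highest and 6 lowest log2 changes for each comparison with 0 h, and the 4 highest and 4 lowest for 72 h against 48 h. These were drawn from called genes with a symbol whose libraries of both groups did not overlap. Part b took, for each list with 3 or more called members, the 2 called members with the largest change and up to 2 called members that moved against the majority. Part c took 16 insulin pathway genes whatever their values. The rule gave 123 genes for each comparison with 0 h and 172 in all. After the data had been seen, part b was limited to lists past the camera test, which left 50 genes at 48 h, 53 at 72 h, 8 for 72 h against 48 h and 78 in all. Members named as exceptions to a list's count, beyond the rule, were chosen after their values were seen, and any other gene outside the rule is marked so where it is named.

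The number of reads per library is unknown, since FPKM values carry no counts, so no counting interval was computed. Relative depth was estimated from the step between the lowest values of a gene in different libraries, over 38 to 64 genes per library. The median standard error of a log2 change was 0.088, and this spread between libraries sets the precision of the text.

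The scripts were tested on simulated data with the 11063 genes and the spread of the real libraries. Of 100 genes changed by 0.5 on the log2 scale, 87% were recovered at 48 h against 0 h and 83% at 72 h against 0 h, and 100% of those changed by 1 in either comparison. False calls numbered 12 and 6, and the F-test made 19. A changed gene set was recovered and 0 of 34 unchanged sets were called. The genes were simulated independently, so this does not measure false calls of the camera test for lists with correlated genes. In the real data the estimated correlation reached 0.77, for ribosomal proteins.

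The settings varied were a pseudocount of 0.1, no filter beyond a mean FPKM above 0, and a mean FPKM of at least 5. Others were median-of-ratios scaling, quantile normalization and rescaling to nuclear protein-coding genes, fits with only the groups compared, with the replicate number as a block (alone and with median-of-ratios scaling), without the variance trend and with library weights, and leaving out each library in turn. Rescaling to equal FPKM sums, removing a trend on gene span from each library, which leaves only the genes with a span, and fitting those genes without that step were added after the data had been seen. Because both comparisons with 0 h use the same 3 control libraries, their agreement was compared with 100 simulated data sets in which nothing changed. Intervals of list medians were 95% bootstrap intervals over 10000 resamples of the genes. They treat genes as independent and leave out the spread between libraries. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.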

Results

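Porcine embryonic fibroblasts are connective tissue cells grown in culture from pig embryos. Their RNA was sequenced at 0 h, as the control, and at 48 h and 72 h after the addition of insulin, the hormone that promotes glucose uptake and the synthesis of fat and protein. Each time had 3 libraries, which the submitters describe as biological replicates. The study's title asks which genes related to metabolism are expressed differently after insulin. FPKM values summed to 494370 ± 5639 (SD, n = 3) at 0 h, 543940 ± 19344 at 48 h and 513990 ± 10455 at 72 h. Between 10761 and 10833 genes per library reached an FPKM of 1. Genes encoded in mitochondrial DNA held 7.34% ± 0.12 of the FPKM sum at 0 h, 7.39% ± 0.31 at 48 h and 6.64% ± 0.62 at 72 h. The read depth is unknown, but the steps between low values placed 48 h replicate 3 at 1.31 times the depth of 0 h replicate 1, and the other libraries at 0.992 to 1.01 times. No untreated cultures of 48 h or 72 h were analysed here, so that in every comparison with 0 h insulin and time in culture vary together.

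The 3 groups of libraries lay apart. Across the 11063 tested genes, the lowest correlation of log2 values between libraries of a group was 0.990, and the highest between groups was 0.987, for a pair of 48 h and 72 h libraries. The first principal component held 58.5% of the variance and placed the 0 h libraries at -31.0 to -28.5, the 48 h libraries at 6.73 to 14.0 and the 72 h libraries at 16.0 to 22.9. The 48 h and 72 h libraries lay on opposite sides of the next component, which held 20.4%. Replicates 1, 2 and 3 of 48 h were spread along it at -23.8, -15.2 and -7.94, and the 72 h libraries lay at 9.46 to 17.2. By limma's moderated F-test, 6704 genes (60.6%) differed among the 3 times.

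**Figure D1:**
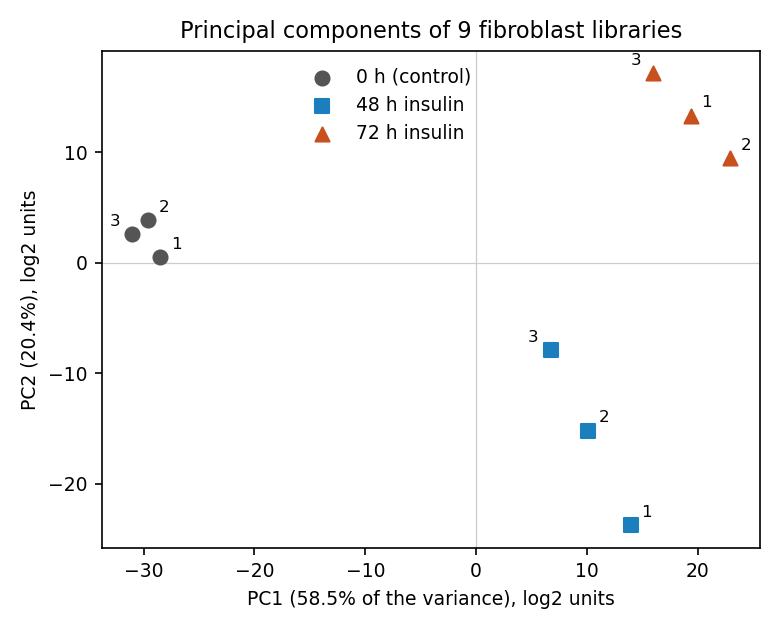
Principal components of log2(FPKM + 1) over 11063 genes, with the first component (58.5% of the variance) on the x axis and the next (20.4%) on the y axis, both in log2 units. Each point is 1 library, numbered by replicate, and the 0 h (circles), 48 h (squares) and 72 h (triangles) libraries form 3 separate groups.

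At 48 h, most tested genes of cholesterol and fatty acid synthesis, of ribosomal proteins, of glycolysis and of the inflammatory and interferon lists were higher than at 0 h, while most genes of mitosis and DNA replication were lower. SCD, the desaturase that makes monounsaturated fatty acids, rose from 38.9 ± 2.34 to 151 ± 14.3 FPKM (mean ± SD, n = 3), a log2 change of 1.93 ± 0.08 (SE). FASN, which encodes fatty acid synthase, rose from 27.8 ± 1.06 to 91.9 ± 3.19 FPKM (1.69 ± 0.06), and SREBF1, a transcription factor that drives lipid synthesis genes, from 8.27 ± 0.366 to 25.7 ± 1.38 (1.53 ± 0.08). In cholesterol synthesis, MVD rose by 1.96 ± 0.10 and IDI1 by 1.89 ± 0.07.

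Of 23 tested genes of cholesterol synthesis, 22 rose and 0 fell (22 adjusted over the list alone), with a median log2 change of 1.34 (camera adjusted p = 4.39e-17, and adjusted p = 0.0343 with an estimated correlation). SCAP, which escorts the SREBP proteins, was the exception at -0.01. In fatty acid synthesis 16 of 21 rose and 3 fell (the same counts adjusted over the list alone), with a median of 0.50 (camera adjusted p = 7.31e-06, but adjusted p = 0.0843 with an estimated correlation). The members that fell were GPAM, ACSL1 and LPIN2, at -0.37, -0.35 and -0.33, which act in glycerolipid assembly and fatty acid activation. FABP3, a carrier of fatty acids in the cytosol, rose from 30.0 ± 0.593 to 136 ± 17.7 FPKM (2.14 ± 0.08).

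SCD (ENSSSCG00000010554) lies on chromosome 14 at 111461560 to 111478033 of Sscrofa11.1, and FASN on chromosome 12 at 922405 to 937560. Both are protein-coding, and the values are for whole genes.

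In glycolysis 15 of 19 rose and 0 fell (15 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 5.6e-05, adjusted p = 0.530 with an estimated correlation). SLC16A3, a lactate exporter, rose by 1.51 ± 0.19 and ENO2, an enolase, by 1.40 ± 0.16, while HK2, a hexokinase, was at 0.13 ± 0.17 (adjusted p = 0.569). Among nuclear genes of oxidative phosphorylation 32 of 44 rose and 0 fell (35 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 7.31e-06, adjusted p = 0.530 with an estimated correlation). ATP5ME rose by 0.62 ± 0.08 and COX7B by 0.69 ± 0.15. The list's call was lost with a trend on gene span removed from each library (median 0.10, adjusted p = 0.125). Only 26 of the 44 genes have a span, but the call was kept in the fit of the genes with a span without that step. All 45 tested cytosolic ribosomal protein genes rose (45 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 5.14e-16, adjusted p = 0.415 with an estimated correlation). RPS20 rose from 578 ± 46.1 to 1454 ± 77.0 FPKM (1.33 ± 0.19) and RPS29 from 212 ± 5.45 to 484 ± 20.2 (1.18 ± 0.10). The 48 h libraries differed among themselves here, with ribosomal protein medians against the 0 h mean of 0.71, 0.56 and 0.43 and oxidative phosphorylation medians of 0.37, 0.27 and 0.16 in replicates 1, 2 and 3. A list of short messenger RNAs of other pathways, some of them mitochondrial, was written after the ribosomal protein result had been seen. It also had more rises than falls, with 18 of 33 genes rising, 1 falling and a median of 0.22.

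Genes of cell division were lower at 48 h. Of 41 mitosis genes 0 rose and 40 fell (40 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 1.82e-25, adjusted p = 0.107 with an estimated correlation), and CDC25B was the exception at -0.11. ANLN, a scaffold of the cytokinetic ring on chromosome 18 at 37647952 to 37710939, fell from 67.2 ± 3.53 to 19.2 ± 3.75 FPKM (-1.77 ± 0.11), and CKAP2, a spindle protein, from 31.0 ± 2.25 to 9.13 ± 1.77 (-1.67 ± 0.12). Of 39 DNA replication genes 0 rose and 34 fell (35 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 1.78e-14, adjusted p = 0.0764 with an estimated correlation). E2F8, a repressor of the E2F family, fell by 1.09 on the log2 scale and CDC45, a part of the replicative helicase, by 0.96. CDT1, MCM2, RFC2, TK1 and TYMS did not pass the test, with changes between -0.28 and -0.13.

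Most tested genes of the inflammatory and interferon lists rose at 48 h. AMCF-II, a porcine chemokine that attracts neutrophils, rose from 2.40 ± 0.148 to 52.5 ± 7.86 FPKM (3.97 ± 0.34). CCL2 (chromosome 12, 40798109 to 40800013), which attracts monocytes, rose from 39.4 ± 4.02 to 349 ± 18.9 (3.12 ± 0.10). CEBPD, a transcription factor of inflammation and fat cell formation, rose from 21.4 ± 6.25 to 92.8 ± 7.09. In the inflammatory list 18 of 24 genes rose and 0 fell (18 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 3.79e-06, adjusted p = 0.415 with an estimated correlation). VCAM1, an adhesion molecule, rose from 0.370 ± 0.135 to 3.65 ± 0.450 FPKM, by 1.76 on the log2 scale and by 3.03 with a pseudocount of 0.1. In the interferon list 22 of 32 rose and 0 fell (22 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 7.31e-06, adjusted p = 0.324 with an estimated correlation), led by BST2 at 1.54 ± 0.07, which tethers viruses to the cell, and PSMB9, a subunit of the immunoproteasome, at 1.19 ± 0.10. In the hypoxia list 13 of 25 rose and 0 fell (13 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.0278, adjusted p = 0.686 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signalling, rose by 1.67 ± 0.16. The hypoxia call was lost without 48 h replicate 2 (median 0.23, adjusted p = 0.0716), without 48 h replicate 3 (0.26, adjusted p = 0.137) and among genes with a mean FPKM of at least 5 (adjusted p = 0.0856).

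More genes fell than rose in the lists of contraction, of mural cells and of unfolded proteins. In the myofibroblast list 15 of 28 genes fell and 6 rose (15 and 6 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.0155, adjusted p = 0.140 with an estimated correlation), and the call was lost among genes with a span (-0.18, adjusted p = 0.0682). ANKRD1, a stretch-responsive gene, fell from 64.1 ± 2.50 to 24.5 ± 1.38 FPKM (-1.35 ± 0.11), while PDGFRA, a growth factor receptor of fibroblasts, rose by 1.43 ± 0.13, TGFBI by 0.69 ± 0.06 and FAP by 0.63 ± 0.08. Of 8 tested pericyte and smooth muscle markers 7 fell and 0 rose (7 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 5.18e-04, adjusted p = 0.324 with an estimated correlation), and ITGA7 was at -0.04. NOTCH3 fell by 1.34 on the log2 scale and MCAM by 0.90. RGS5, HIGD1B, KCNJ8 and ABCC9, the other markers of that list, had a mean FPKM below 1 at each time and were not tested. In the unfolded protein list 12 of 23 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00213, adjusted p = 0.182 with an estimated correlation). SEL1L, which acts in degradation of misfolded proteins, fell from 79.1 ± 3.58 to 41.9 ± 18.9 FPKM, with 48 h values of 23.1, 41.7 and 60.9, and its log2 change was -0.64 without 48 h replicate 1, over 1.5 times smaller than with it. ATF6, a sensor of unfolded proteins, fell by 0.55 ± 0.13. The members that rose were HERPUD1 at 0.27 and SEC61B at 0.22, and both calls were lost under quantile normalization (adjusted p = 0.0762 and 0.355), at equal FPKM sums (0.0617 and 0.165) and with the gene span trend removed (0.0870 and 0.991). HERPUD1 was at 0.16 after rescaling to protein-coding genes. SEC61B was also lost after rescaling to protein-coding genes (0.0875) and without 0 h replicate 2 (0.0548).

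The largest falls were in FOS and FOSB, transcription factor genes induced within minutes of a stimulus, at -2.68 ± 0.15 and -2.49 ± 0.16. JAG1, a ligand of Notch receptors, fell from 36.6 ± 1.61 to 8.49 ± 1.70 FPKM (-2.00 ± 0.13). CYP1A1, a target of the aryl hydrocarbon receptor, fell from 3.54 ± 0.330 to 0.230 ± 0.0346 FPKM (-1.88 on the log2 scale, and -3.47 with a pseudocount of 0.1), ENC1 by 1.81 on the log2 scale and COL5A3, a collagen chain, by 1.81.

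Of the 16 insulin pathway genes 12 were tested, and 8 of them were called at 48 h. Of these 5 rose, among them SREBF1, FASN and SCD, as described above. INSR, the insulin receptor, fell from 1.41 ± 0.196 to 0.813 ± 0.228 FPKM (-0.41 ± 0.11, adjusted p = 0.0106, but -0.75 with a pseudocount of 0.1 and -0.26 with the gene span trend removed), IGF1R, its relative that binds IGF1, from 22.1 ± 0.832 to 15.2 ± 1.66 (-0.51 ± 0.08), and TXNIP, an inhibitor of glucose uptake, from 9.01 ± 0.647 to 3.77 ± 1.35 (-1.11 ± 0.27, adjusted p = 0.00594). IRS1 was at 0.06 ± 0.09, IRS2 at 0.01 ± 0.10 and IGFBP5 at -0.03 ± 0.18. HK2, not called as reported, was called with library weights (0.38, adjusted p = 0.00303). In the wider list of insulin and PI3K signalling 7 of 33 genes rose and 8 fell (7 and 7 adjusted over the list alone), and the camera adjusted p was 0.881.

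The other 21 lists did not pass the camera test at 48 h, with adjusted p from 0.0998 to 0.985. More members rose than fell among FOXO targets (10 and 6 of 23), the pentose phosphate and one-carbon list (8 and 4 of 17), fatty acid oxidation (10 and 4 of 24), the TCA cycle (13 and 3 of 24), genes encoded in mitochondrial DNA (5 and 1 of 13), lysosome and autophagy (13 and 2 of 35), adipocyte differentiation (5 and 2 of 12) and glucose transport and storage (5 and 3 of 16). Fewer rose than fell among immediate early genes (7 and 12 of 25), fibrillar matrix (10 and 13 of 36), CDK inhibitors and p53 targets (7 and 11 of 26), skeletal muscle markers (1 and 3 of 7) and neural markers (1 and 3 of 6). Ribosome biogenesis (9 and 5 of 34), ATF4 targets (10 and 9 of 28), heat shock (4 and 4 of 17), the IGF system (6 and 5 of 14), matrix proteases (8 and 6 of 17), amino acid transport (6 and 3 of 18), gluconeogenesis (3 and 1 of 8) and cartilage and bone markers (4 and 2 of 8) went both ways. The median, the mean and the test differed in sign for insulin signalling, the IGF system, glucose transport, heat shock, fibrillar matrix, ATF4 targets and cartilage and bone markers. Adjusted over the list alone, the counts were the same except for the pentose list (8 and 5), fatty acid oxidation (11 and 4), ribosome biogenesis (6 and 5), fibrillar matrix (10 and 14), ATF4 targets (11 and 10) and cartilage and bone markers (4 and 3).

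Altogether 5524 of 11063 genes were called at 48 h, 3048 higher and 2476 lower, and 173 and 158 of them by at least 1 on the log2 scale. The 3 libraries of each group did not overlap for 60.0% of genes, where chance gives 10%. The split depends on the scaling. The share of calls that were higher was 55.2% as deposited, 39.0% (2156 higher and 3366 lower) after rescaling to protein-coding genes and 34.7% (1959 and 3691) at equal FPKM sums, a setting that moved the median gene by -0.12. At equal sums the medians were 1.21 for cholesterol synthesis, 0.43 for ribosomal proteins, 0.13 for oxidative phosphorylation, with 17 genes rising and 4 falling, and -1.24 for mitosis. Several list medians moved by more than 1.5 times. Under quantile normalization they were 0.27 for glycolysis (9 of 19 rising), 0.15 for oxidative phosphorylation (16 of 44 rising and 4 falling), 0.34 for ribosomal proteins, 0.19 for hypoxia and -0.31 for the myofibroblast list. At equal sums they were 0.20 for interferon response, 0.17 for hypoxia, -0.34 for the myofibroblast list and -0.34 for the unfolded protein list. After rescaling to protein-coding genes they were 0.16 for oxidative phosphorylation, 0.20 for hypoxia, -0.32 for the myofibroblast list and -0.31 for the unfolded protein list. With the gene span trend removed they were 0.30 for ribosomal proteins and -0.34 for the unfolded protein list. The 5 pericyte markers with a mean FPKM of at least 5 had a median of -0.70. The counts of changes of at least 1 were 308 higher and 266 lower with a pseudocount of 0.1, and 101 were higher with the gene span trend removed. That setting holds only the 9310 genes with a span, of which 140 were higher without the removal.

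**Figure D2:**
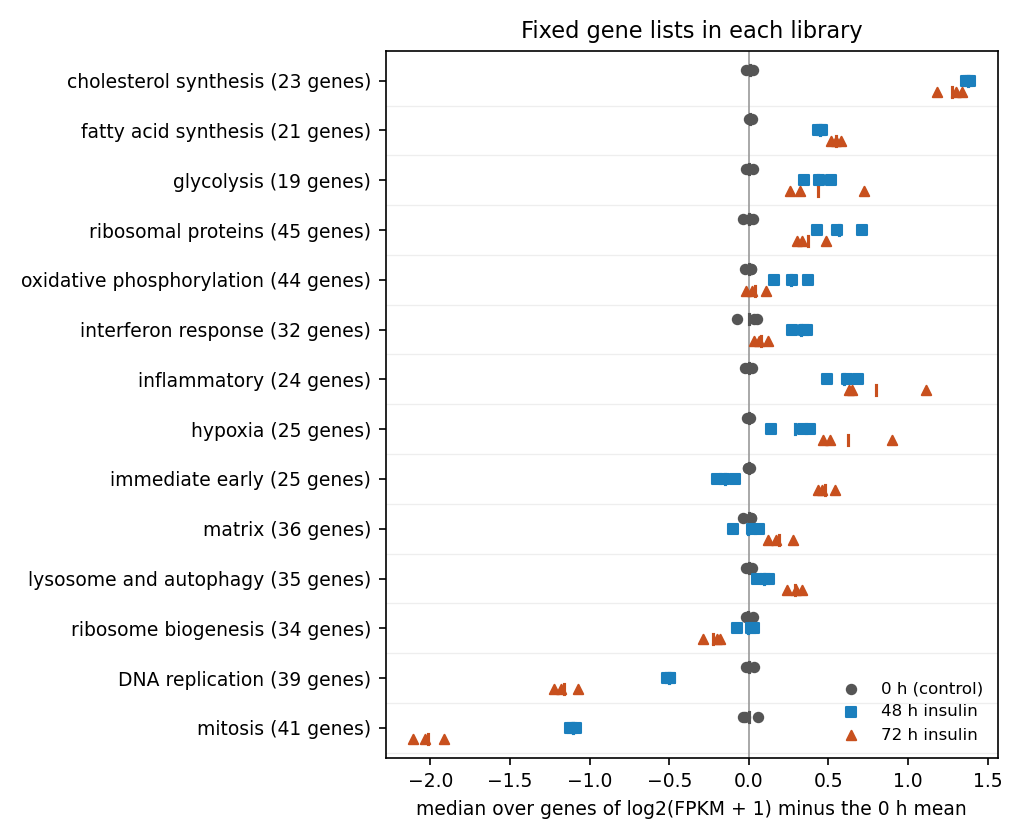
Median over the genes of 14 fixed lists of log2(FPKM + 1) minus the 0 h mean, on the x axis, for each of 9 libraries, with circles for 0 h, squares for 48 h, triangles for 72 h and a vertical bar at the mean of each group. Cholesterol synthesis lies near 1.3 to 1.4 at 48 h, mitosis lies near -1.1 at 48 h and -1.9 to -2.1 at 72 h, and 72 h replicate 2 stands to the right of the other 72 h libraries for glycolysis, hypoxia and inflammatory genes.

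At 72 h most tested genes of cholesterol and fatty acid synthesis were again higher than at 0 h, most cell division genes were lower, and most genes of the hypoxia, lysosome and immediate early lists were higher. SCD reached 213 ± 7.50 FPKM (2.42 ± 0.08, SE), FASN 101 ± 5.84 (1.82 ± 0.06), SREBF1 32.8 ± 3.03 (1.86 ± 0.08) and FABP3 164 ± 4.13 (2.41 ± 0.08). HMGCS1, the synthase at the start of cholesterol synthesis, on chromosome 16 at 27936225 to 27957261, rose from 24.0 ± 0.593 at 0 h to 89.2 ± 3.92 FPKM (1.85 ± 0.08, n = 3). INSIG1, which retains the SREBP complex in the endoplasmic reticulum, rose by 1.81 ± 0.07. In cholesterol synthesis 22 of 23 genes rose and 0 fell (22 adjusted over the list alone), with a median of 1.29 (camera adjusted p = 9.35e-17, and adjusted p = 0.0186 with an estimated correlation). SCAP was again the exception, at 0.03. In fatty acid synthesis 14 of 21 rose and 3 fell (the same adjusted over the list alone), with a median of 0.50 (camera adjusted p = 3.16e-06, adjusted p = 0.0616 with an estimated correlation). The members that fell were GPAM, LPIN2 and ACSL1, at -0.34, -0.26 and -0.26.

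Cell division genes were lower at 72 h by larger amounts. Of 41 mitosis genes 40 fell and 0 rose (41 adjusted over the list alone), with a median of -1.99 (camera adjusted p = 1.18e-32, adjusted p = 0.0616 with an estimated correlation), and BUB3 was at -0.20. CDCA3 fell from 63.3 ± 4.90 to 8.69 ± 2.38 FPKM (-2.75 ± 0.14), ANLN to 10.6 ± 0.545 (-2.55 ± 0.11), CDCA8, a part of the chromosomal passenger complex, by 2.51 on the log2 scale, CKAP2 by 2.49 and KIF11, a spindle motor, by 2.45. All 39 DNA replication genes fell (39 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 5.92e-25, and adjusted p = 0.0186 with an estimated correlation). E2F8 fell by 1.99 on the log2 scale, and CDC45, on chromosome 14 at 51133111 to 51158604, from 27.8 ± 1.85 to 6.49 ± 0.846 FPKM (-1.95 ± 0.09). In ribosome biogenesis 18 of 34 fell and 0 rose (18 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1.74e-04, adjusted p = 0.270 with an estimated correlation). LYAR fell by 0.91 and NCL, which encodes nucleolin, by 0.89. Cytosolic ribosomal protein genes went the other way, with 43 of 45 rising and 0 falling (44 adjusted over the list alone) and a median of 0.37 (camera adjusted p = 1.43e-11, adjusted p = 0.390 with an estimated correlation). RPL27 and RPS9 did not pass, at 0.10 and 0.25.

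Matrix genes lay on both sides of their 0 h values at 72 h, as at 48 h, when 10 of 36 rose and 13 fell. COL6A3, a chain of collagen VI on chromosome 15 at 137011549 to 137103687, rose from 40.1 ± 2.75 to 195 ± 13.9 FPKM (2.25 ± 0.08), and LUM, which encodes the proteoglycan lumican, from 12.7 ± 0.486 to 48.3 ± 4.43 (1.84 ± 0.07). ELN, elastin, fell by 0.88 on the log2 scale, and TNC, tenascin C, from 1082 ± 14.9 to 623 ± 90.8 FPKM (-0.81 ± 0.10). In the fibrillar matrix list 16 of 36 rose and 8 fell (16 and 8 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.00713, adjusted p = 0.390 with an estimated correlation), and the call was lost under quantile normalization (median 0.07, adjusted p = 0.0903). ANKRD1 fell further, to 7.23 ± 1.42 FPKM (-3.00 ± 0.11). Of the 8 pericyte and smooth muscle markers 7 fell and 0 rose (7 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 0.00113, adjusted p = 0.374 with an estimated correlation), and ITGA7 was at 0.06. MCAM fell by 1.29 and NOTCH3 by 1.08. Without the filter beyond a mean FPKM above 0 this call was lost (median -0.30, adjusted p = 0.0800). In the lysosome and autophagy list 21 of 35 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 5.83e-05, adjusted p = 0.0659 with an estimated correlation). NPC1, which exports cholesterol from lysosomes, rose by 0.97 ± 0.08 and CTSL, a cathepsin, by 1.08 ± 0.17, while ATG16L1 fell by 0.27.

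Most tested genes of the inflammatory, hypoxia, glycolysis and FOXO target lists were higher at 72 h, and in all 4 lists 72 h replicate 2 stood above the other 72 h libraries. In the inflammatory list 19 of 24 rose and 0 fell (20 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 7.44e-08, adjusted p = 0.374 with an estimated correlation). CCL2 was at 220.1 ± 30.0 FPKM (2.45 ± 0.10) and AMCF-II at 18, 62.3 and 22.3 FPKM in the 3 libraries (3.16 ± 0.34, and 2.63 without replicate 2). C3, a complement component, rose from 0.107 ± 0.0153 to 5.82 ± 5.02 FPKM, with 11.6 FPKM in replicate 2 (2.38 ± 0.36, 1.82 without it and 4.51 with a pseudocount of 0.1). In the hypoxia list 21 of 25 rose and 0 fell (22 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 6.12e-08, adjusted p = 0.374 with an estimated correlation). In glycolysis 15 of 19 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 4.19e-05, adjusted p = 0.458 with an estimated correlation). Of the glycolysis list, ENO2 rose by 1.95 ± 0.16 and SLC16A3 by 1.65 ± 0.19, while ALDOC, an aldolase, fell by 0.47. DDIT4, of the hypoxia and FOXO target lists, rose by 1.52 ± 0.16. ENO2 stands in the hypoxia list too, so these lists share members and are not independent. Replicates 1, 2 and 3 had medians of 0.46, 0.90 and 0.51 for hypoxia, 0.63, 1.11 and 0.65 for inflammatory genes and 0.26, 0.72 and 0.32 for glycolysis. Without replicate 2 the 3 medians were 0.47, 0.66 and 0.28, and the glycolysis value moved by more than 1.5 times. Among FOXO targets 13 of 23 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 8.23e-04, adjusted p = 0.377 with an estimated correlation). Replicates 1, 2 and 3 had FOXO target medians of 0.43, 0.61 and 0.43. CDKN1C, a CDK inhibitor, rose by 1.33 ± 0.11, while GADD45A fell by 0.50 and CAT, catalase, by 0.32.

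Among immediate early genes 16 of 25 rose and 6 fell at 72 h (16 and 6 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.00163, adjusted p = 0.374 with an estimated correlation). EGR1 rose by 1.39 ± 0.09, FOSB by 1.39 ± 0.16 and FOS by 0.88 ± 0.15, while FOSL1 fell by 0.98 and DUSP5, a phosphatase that acts on ERK, by 0.96. NUPR1, a stress-induced regulator of transcription, rose from 129 ± 1.52 to 669 ± 48.3 FPKM (2.36 ± 0.09).

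Of the 12 tested insulin pathway genes 6 were called at 72 h, and all 6 rose, among them SREBF1, FASN, SCD and HK2. HK2 rose by 0.50 ± 0.17 (adjusted p = 0.0341), with 21.1 FPKM in replicate 2 against 13.5 and 13.9, and the call was lost without that library (0.31, adjusted p = 0.119) or without any of the 0 h libraries (adjusted p = 0.0971, 0.0592 and 0.0707 for replicates 1, 2 and 3). It was also lost with no filter (0.0951), at equal FPKM sums (0.0562) and after rescaling to protein-coding genes (0.0505). INSR was at -0.06 ± 0.11, IGF1R at -0.04 ± 0.08, IRS1 at 0.05 ± 0.09, IRS2 at 0.21 ± 0.10 and TXNIP at 0.28 ± 0.27, none of them called, except that IRS2 was called with library weights (0.22, adjusted p = 0.0416). IGFBP5, an IGF-binding protein, was at 0.23 ± 0.18 (adjusted p = 0.331), but 72 h replicate 2 had 149 FPKM against 270 and 259 in the others, and without it the gene was called at 0.50 (adjusted p = 8.8e-04).

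The other 21 lists did not pass the camera test at 72 h, with adjusted p from 0.0954 to 0.993. More members rose than fell in insulin and PI3K signalling (9 and 4 of 33), the IGF system (6 and 2 of 14), the pentose phosphate and one-carbon list (8 and 4 of 17), fatty acid oxidation (9 and 6 of 24), glucose transport and storage (6 and 3 of 16), adipocyte differentiation (6 and 2 of 12) and cartilage and bone markers (4 and 2 of 8). Fewer rose than fell in the myofibroblast list (8 and 16 of 28), the unfolded protein list (3 and 8 of 23), heat shock (0 and 6 of 17), mitochondrial DNA (0 and 4 of 13), skeletal muscle markers (1 and 4 of 7) and neural markers (1 and 4 of 6). The counts were close for oxidative phosphorylation (7 and 5 of 44), the TCA cycle (6 and 7 of 24), ATF4 targets (7 and 8 of 28), interferon response (9 and 9 of 32), p53 targets (7 and 5 of 26), matrix proteases (8 and 6 of 17), amino acid transport (3 and 3 of 18) and gluconeogenesis (2 and 1 of 8). The median, the mean and the test differed in sign for the TCA cycle, ATF4 targets and amino acid transport. The counts adjusted over the list alone were the same except for the IGF system (7 and 2), glucose transport (7 and 3), fatty acid oxidation (10 and 7), oxidative phosphorylation (4 and 2), matrix proteases (9 and 6), ATF4 targets (7 and 9), heat shock (0 and 5), interferon response (10 and 9) and cartilage and bone markers (5 and 2).

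In all, 5029 of 11063 genes were called at 72 h, 2542 higher and 2487 lower, with 237 and 339 of them changed by at least 1 on the log2 scale. The split was 2216 higher and 2843 lower after rescaling to protein-coding genes. It was 2159 and 2927 at equal FPKM sums, and 2595 and 2438 with median-of-ratios scaling. Groups did not overlap for 58.6% of genes, where chance gives 10%. With a pseudocount of 0.1, 382 were higher by at least 1, and among genes with a mean FPKM of at least 5, 219 were lower by at least 1. The median of ribosomal proteins was 0.22 under quantile normalization (34 of 45 rising), and that of fibrillar matrix 0.10 at equal FPKM sums.

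Between 48 h and 72 h, most tested genes of the immediate early and fibrillar matrix lists rose, and most of those of cell division, ribosome biogenesis and interferon response fell. FOS, on chromosome 7 at 98449508 to 98451971, was at 172 ± 5.12, 26.4 ± 6.35 and 321 ± 55.4 FPKM (mean ± SD, n = 3) at 0 h, 48 h and 72 h, a difference of 3.56 ± 0.15 (SE) between 48 h and 72 h. FOSB differed by 3.87 ± 0.16 and EGR1, at 33.5 ± 0.5, 9.89 ± 1.17 and 89.6 ± 9.33 FPKM, by 3.06 ± 0.09. GPNMB, a glycoprotein of lysosomes and melanosomes, rose from 3.30 ± 0.955 to 15.6 ± 1.29 FPKM (1.97 ± 0.14). SST (ENSSSCG00000033815), which encodes the hormone somatostatin and lies on chromosome 13 at 125337560 to 125338742, had 25.1 ± 1.62 FPKM at 0 h, 97.9 ± 4.15 at 48 h and 13.4 ± 2.49 at 72 h. Its changes were 1.93 ± 0.11 at 48 h, -0.87 ± 0.11 at 72 h and -2.79 ± 0.11 between them. ID1, a target of BMP signalling, on chromosome 17 at 35316518 to 35317742, went from 142 ± 16.3 to 32.3 ± 3.44 FPKM (-2.11 ± 0.09). ANKRD1 fell by 1.65 on the log2 scale.

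**Figure D3:**
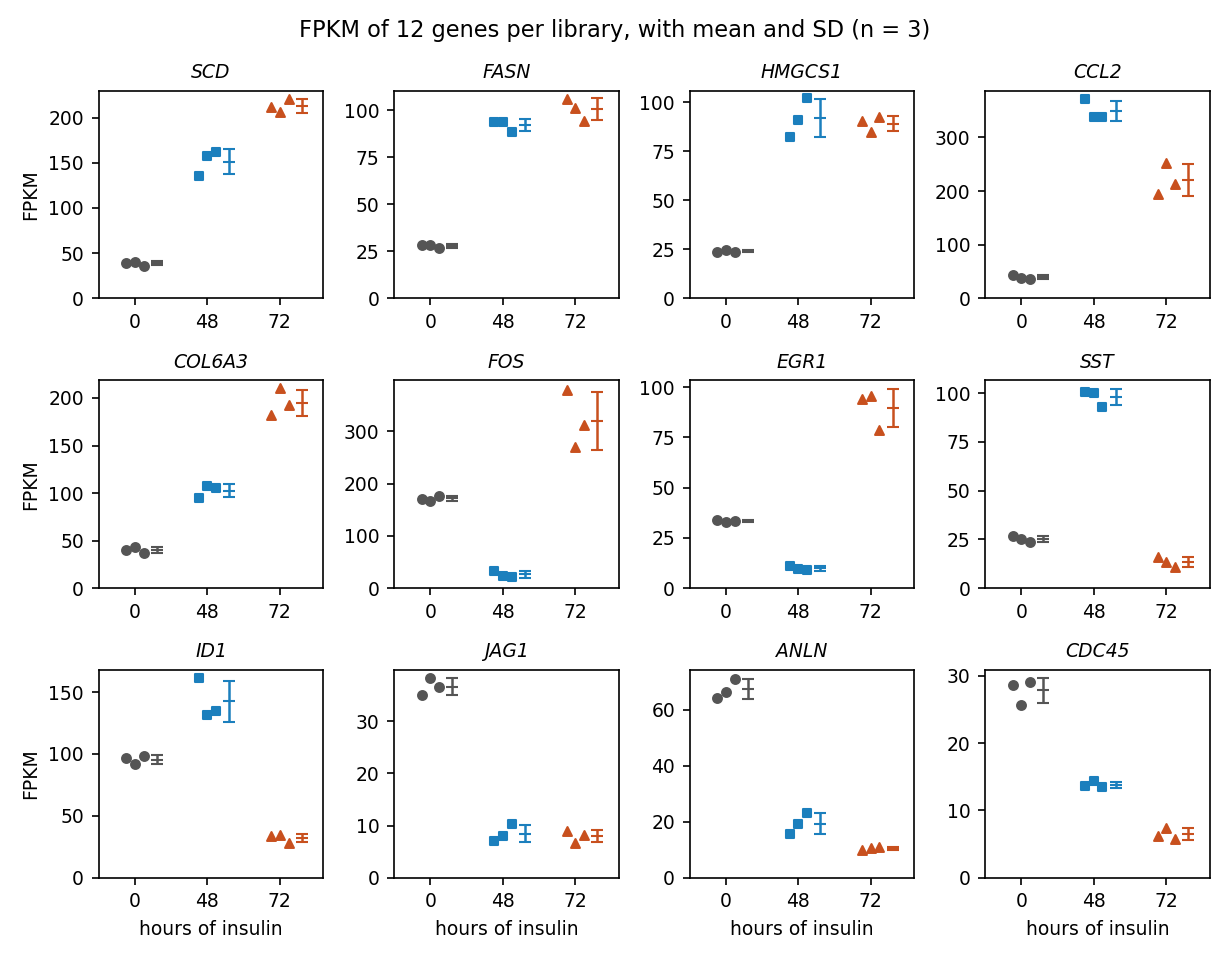
FPKM of 12 genes (y axis, from 0) in each library by hours of insulin (x axis), with the mean and SD of 3 libraries beside the points. SCD, FASN and HMGCS1 are higher at 48 h and 72 h than at 0 h, ANLN and CDC45 are lower, and FOS, EGR1, SST and ID1 move in opposite directions at 48 h and 72 h.

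COX6B2 fell by 1.80 ± 0.47 from 48 h to 72 h (adjusted p = 0.0190, and -3.20 with a pseudocount of 0.1), but its 72 h values were 0.580, 4.45 and 0 FPKM. The call was lost without 48 h replicate 1 or 2 (adjusted p = 0.0583 and 0.0536), without 72 h replicate 1 or 3 (0.0664 and 0.0565) and with no filter (0.0684).

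In the 72 h against 48 h comparison 38 of 41 mitosis genes fell and 0 rose (39 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 7.66e-27, adjusted p = 0.106 with an estimated correlation). The exceptions were BUB3 at 0.13, CENPI at -0.25 and ECT2 at -0.23. Of 39 DNA replication genes 37 fell and 0 rose (38 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 6.29e-23, and adjusted p = 0.0449 with an estimated correlation), and POLA1 and POLE2 were at -0.26 and -0.25. In ribosome biogenesis 20 of 34 fell and 1, MYC, rose (23 and 1 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 3.16e-06, adjusted p = 0.109 with an estimated correlation). In fibrillar matrix 20 of 36 rose and 0 fell (22 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 3.82e-10, adjusted p = 0.107 with an estimated correlation), led by COL6A3 at 0.92 ± 0.08. Among immediate early genes 13 of 25 rose and 5 fell (15 and 5 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 1.27e-07, adjusted p = 0.106 with an estimated correlation). In the hypoxia list 11 of 25 rose and 0 fell (13 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 3.71e-07, adjusted p = 0.328 with an estimated correlation). In the lysosome list 13 of 35 rose and 0 fell (15 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 8.63e-06, adjusted p = 0.106 with an estimated correlation), which was 0.18 without 48 h replicate 3. Other settings also moved list medians by more than 1.5 times. Library weights gave 0.18 for hypoxia and 0.19 for lysosome, equal FPKM sums gave 0.19 for lysosome, and ribosome biogenesis was at -0.20 with the gene span trend removed.

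Lists of mitochondrial genes had more falls than rises from 48 h to 72 h. In oxidative phosphorylation 17 of 44 fell and 0 rose (24 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 1.08e-06, adjusted p = 0.336 with an estimated correlation). Of 13 genes encoded in mitochondrial DNA 6 fell and 0 rose (8 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.00343, adjusted p = 0.369 with an estimated correlation). In the TCA cycle 9 of 24 fell and 1 rose, IDH1 (11 and 1 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.0153, adjusted p = 0.135 with an estimated correlation), and the call was lost under quantile normalization (-0.09, adjusted p = 0.116) and at equal FPKM sums (-0.08, adjusted p = 0.0599). In the interferon list 19 of 32 fell and 1 rose, IFI6 (19 and 1 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 7.42e-06, adjusted p = 0.247 with an estimated correlation). Of 45 ribosomal protein genes 4 fell and 0 rose (0 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 1.65e-04, adjusted p = 0.549 with an estimated correlation). The short messenger RNAs of other pathways also had more falls than rises, with 19 of 33 falling, 0 rising and a median of -0.26. In the heat shock list 6 of 17 fell and 0 rose (10 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.00812, adjusted p = 0.328 with an estimated correlation), and the call was lost without 72 h replicate 2 (-0.14, adjusted p = 0.0779). With a trend on gene span removed from each library, the calls of ribosomal protein, mitochondrial DNA and heat shock genes were lost (adjusted p = 0.618, 0.584 and 0.148). In that setting oxidative phosphorylation was at -0.09 (4 of 26 falling, adjusted p = 0.0255) and the TCA cycle at -0.10 (4 of 24 falling, adjusted p = 0.0297). Under quantile normalization the medians were -0.14 for mitochondrial DNA, -0.10 for ribosomal proteins and -0.10 for heat shock. At equal FPKM sums they were -0.14 for oxidative phosphorylation, -0.16 for mitochondrial DNA, -0.10 for ribosomal proteins and -0.08 for heat shock. After rescaling to protein-coding genes they were -0.10 for the TCA cycle, -0.12 for ribosomal proteins and -0.10 for heat shock.

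FOXO targets, p53 targets and the unfolded protein list also had more rises than falls from 48 h to 72 h. Among FOXO targets 6 of 23 rose and 0 fell (6 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 6.81e-04, adjusted p = 0.328 with an estimated correlation), which was 0.11 without 48 h replicate 1 and 0.30 with the gene span trend removed. TXNIP rose by 1.39 ± 0.27, and by 0.88 with library weights. Among p53 targets and CDK inhibitors 9 of 26 rose and 4 fell (11 and 4 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.00654, adjusted p = 0.106 with an estimated correlation). In the unfolded protein list 9 of 23 rose and 0 fell (9 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.00593, adjusted p = 0.176 with an estimated correlation), which was 0.16 after rescaling to protein-coding genes, 0.17 at equal FPKM sums and 0.14 with the gene span trend removed. SEL1L differed by 0.92 ± 0.26, ATF6 by 0.40 ± 0.13, IGF1R by 0.47 ± 0.08 and INSR by 0.35 ± 0.11. Without 48 h replicate 1 SEL1L was at 0.55, ATF6 at 0.22 and INSR at 0.24, and the ATF6 and INSR calls were lost (adjusted p = 0.0711 and 0.13). The calls of SEL1L, ATF6 and INSR were lost without 3, 8 and 7 of the 9 libraries, each left out in turn.

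The other 19 lists did not pass the camera test between 48 h and 72 h, with adjusted p from 0.0594 to 0.929. Those with more rises than falls were insulin and PI3K signalling (5 and 3 of 33), the IGF system (2 and 1 of 14), glycolysis (2 and 1 of 19), glucose transport and storage (4 and 1 of 16), gluconeogenesis (2 and 1 of 8), fatty acid synthesis (4 and 2 of 21), matrix proteases (5 and 0 of 17), the myofibroblast list (9 and 3 of 28), cartilage and bone markers (3 and 0 of 8) and pericyte markers (2 and 1 of 8). Those with more falls were the pentose phosphate and one-carbon list (1 and 5 of 17), cholesterol synthesis (2 and 7 of 23), fatty acid oxidation (1 and 5 of 24), ATF4 targets (2 and 5 of 28), skeletal muscle markers (0 and 2 of 7) and neural markers (0 and 2 of 6). Adipocyte differentiation (2 and 2 of 12), inflammatory genes (5 and 5 of 24) and amino acid transport (3 and 3 of 18) were even. The sign differed between the median, the mean and the test for the inflammatory, myofibroblast, adipocyte, amino acid transport and pericyte lists. With p adjusted over the list alone, the counts were the same except for the IGF system (3 and 1), glycolysis (1 and 1), cholesterol synthesis (2 and 8), adipocyte differentiation (3 and 2), matrix proteases (5 and 1), the myofibroblast list (10 and 5) and inflammatory genes (7 and 5).

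A total of 2814 genes were called between 48 h and 72 h, 1014 higher and 1800 lower, with 28 and 56 changed by at least 1 on the log2 scale, and groups did not overlap for 38.9% of genes, where chance gives 10%. The share of calls that were higher was 36.0% as deposited, 47.5% (1301 higher and 1439 lower) with median-of-ratios scaling, 48.6% (1312 and 1387) with quantile normalization, 50.2% (1283 and 1272) after rescaling to protein-coding genes and 55.9% (1426 and 1127) at equal FPKM sums. The count was 1839 with only these 2 groups in the fit, and it was 1727 without 48 h replicate 2. Higher calls numbered 589 without that library, 624 without 72 h replicate 1 and 651 without 72 h replicate 3, and lower calls 1138 without 48 h replicate 2. Of the changes of at least 1, 44 were higher without 48 h replicate 3 and 56 with a pseudocount of 0.1. In the same way 36 were lower without 72 h replicate 1, 140 with a pseudocount of 0.1, 37 after rescaling to protein-coding genes, 33 at equal FPKM sums and 89 with library weights. With the gene span trend removed 30 were lower, against 41 of the same 9310 genes without the removal.

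The changes at 48 h and 72 h against 0 h were compared across genes. Over genes, which are not independent replicates, their correlation was 0.799, against 0.50 ± 0.0671 in simulated data with no change and the same controls. Their covariance was 0.160 against 0.00851 simulated, a difference of 0.151. Both calls were higher for 1890 genes and lower for 1631, where independent lists would share 700 and 557. In the simulated data 0 genes were called in both, but nothing changed there. Part of the excess may still come from the shared 0 h libraries, since 3 controls cannot be split into groups of at least 2. Opposite calls were made for 67 genes, against 1254 for independent lists, 23 of them lower at 48 h and higher at 72 h and 44 the reverse. Only 7 had both changes of at least 0.5, namely FOSB, FOS, EGR1, SST, ID1, GPNMB and DUSP6. DUSP6, a phosphatase that acts on ERK, was at 11.6 ± 0.366, 7.14 ± 0.112 and 20.6 ± 1.54 FPKM, and was chosen after its values were seen.

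The lists of endothelial, epithelial and blood cell markers had 4, 2 and 4 tested members and entered no set test. Among endothelial markers 2 fell and 1 rose at 48 h and at 72 h, among epithelial markers 1 rose and 1 fell at each time, and among blood cell markers 2 rose and 1 fell at 48 h and 2 rose and 2 fell at 72 h, with the same counts adjusted over the list alone. The tested endothelial markers were ERG at 8.21 FPKM at 0 h and 16.6 at 72 h, FLT1 at 6.04 and 1.81, CLDN5 at 5.75 and 1.49, and PECAM1 at 0.787 and 1.09. The tested epithelial markers were KRT8 at 5.98 FPKM at 0 h and 8.95 at 72 h, with 11.8 at 48 h, and ESRP1 at 2.29 and 1.23 at 0 h and 72 h. Among tested blood cell markers CD74, a chaperone of MHC class II, was at 133 FPKM at 0 h, 219.7 at 48 h and 188 at 72 h, and at 0 h and 72 h CD14 was at 1.83 and 4.05, LCP1 at 3.94 and 1.80 and CORO1A at 1.18 and 0.470. The other 8, 11 and 13 measured markers of these lists did not pass the filter. DES, which encodes desmin and stands in the skeletal muscle and pericyte lists, was abundant at 1440 FPKM at 0 h and fell to 889 at 48 h and 919 at 72 h. DES was chosen after its values were seen.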

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

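The tests of recent handling of the 72 h cultures, of transcript length as the whole cause of the ribosomal protein rise and of a gene span trend, and the setting with only the genes that have a span, were chosen only after the result was seen. Listed here are results whose change from 0 h differed between 48 h and 72 h, by the limma test of 72 h against 48 h. This holds for 43 of the 78 named genes, 22 of them higher and 21 lower at 72 h, and, by the camera test, for 16 of the 35 lists, of which 1, DNA replication, kept its call with an estimated correlation (adjusted p = 0.0449). Insulin and time in culture vary together in these differences too.

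Among the genes that were higher at 72 h, the differences on the log2 scale were 3.87 for FOSB, 3.56 for FOS, 3.06 for EGR1, 1.97 for GPNMB and 1.39 for TXNIP. In matrix and fibroblast genes they were 0.92 for COL6A3, 0.53 for TGFBI, 0.51 for FAP, 0.50 for LUM and 0.41 for PDGFRA. In lipid genes they were 0.49 for SCD, 0.34 for SREBF1, 0.28 for FABP3 and 0.26 for NPC1. The receptor genes IGF1R, INSR and NOTCH3 differed by 0.47, 0.35 and 0.26, the stress genes SEL1L, NUPR1, ATF6 and HERPUD1 by 0.92, 0.76, 0.40 and 0.17, and ENO2 by 0.56. Some of these calls were lost with 1 library left out. The ATF6 call was lost without any library but 48 h replicate 3, that of PDGFRA without any but 48 h replicate 3 and 72 h replicate 1, and that of HERPUD1 without any but 48 h replicate 3 and 72 h replicate 3. The INSR call was lost without any but 0 h replicate 2 and 48 h replicate 3, and that of NPC1 without any but these and 72 h replicate 2. FABP3 lost its call without 48 h replicate 2 or any 72 h library, ENO2 without 48 h replicate 1 or 3 or 72 h replicate 2 or 3, SEL1L without 48 h replicate 2 or 72 h replicate 1 or 2, and NOTCH3 without 72 h replicate 1 or 3. With 1 library left out the values were 0.22 to 0.55 for ATF6, 0.24 to 0.55 for PDGFRA, 0.15 to 0.19 for HERPUD1, 0.24 to 0.40 for INSR and 0.20 to 0.34 for NPC1. They were 0.18 to 0.36 for FABP3, 0.36 to 0.72 for ENO2, 0.55 to 1.23 for SEL1L and 0.20 to 0.31 for NOTCH3. The lowest of these moved by more than 1.5 times without 48 h replicate 1 for SEL1L and ATF6, without 72 h replicate 2 for ENO2 and PDGFRA and without 48 h replicate 3 for FABP3. Library weights gave 0.22 for ENO2 and 0.88 for TXNIP, a pseudocount of 0.1 gave 0.65 for INSR, and with the gene span trend removed FABP3 was at 0.42 and HERPUD1 at 0.28.

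Among the genes that were lower at 72 h, SST differed by -2.79, ID1 by -2.11, COX6B2 by -1.80 and ANKRD1 by -1.65. The cell division genes CDCA3, CDCA8, CDC45, E2F8, KIF11, CKAP2 and ANLN differed by -1.42, -1.15, -0.99, -0.90, -0.89, -0.82 and -0.79. The nucleolar genes LYAR and NCL differed by -0.74 and -0.47, FOSL1 and DUSP5 by -0.77 and -0.36, CCL2 by -0.67, ALDOC by -0.59, ENC1 by -0.47 and MCAM by -0.40. In cholesterol synthesis MVD differed by -0.42 and IDI1 by -0.21. The IDI1 call was lost without any library but 48 h replicate 3 (-0.26 to -0.15 with 1 left out). NCL (-0.64 to -0.37) lost its call without 0 h replicate 3, 48 h replicate 1 or 2 or 72 h replicate 1 or 2. MCAM (-0.47 to -0.29) lost it without 48 h replicate 1 or 72 h replicate 1 or 2. DUSP5 (-0.46 to -0.30) lost it without 48 h replicate 1 or 72 h replicate 2 or 3. ENC1 (-0.57 to -0.33) lost it without 72 h replicate 2. COX6B2 lost its call without 48 h replicate 1 or 2 or 72 h replicate 1 or 3 (-1.73, -1.79, -1.61 and -1.28). Library weights gave -0.26 for MCAM and -0.19 for DUSP5, equal FPKM sums gave -0.13 for IDI1, and with the gene span trend removed MVD was at -0.28. In all, 15 of the 43 gene calls were lost in at least 1 setting, and all 15 of them with at least 1 library left out.

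The list medians of this difference were 0.43 for immediate early genes, 0.31 for hypoxia, 0.28 for fibrillar matrix, 0.21 for p53 targets and CDK inhibitors, 0.18 for FOXO targets, 0.12 for lysosome and autophagy and 0.0937 for the unfolded protein list. They were -0.87 for mitosis, -0.68 for DNA replication, -0.30 for ribosome biogenesis, -0.30 for interferon response, -0.24 for mitochondrial DNA, -0.22 for oxidative phosphorylation, -0.18 for ribosomal proteins, -0.17 for heat shock and -0.16 for the TCA cycle.

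FOS, FOSB and EGR1 were higher at 72 h than at 48 h. No single library decides this, since the lowest of their differences with 1 library left out was 2.98. Handling of the 72 h cultures shortly before harvest stays open. Other immediate early genes had a median difference of 0.30 (bootstrap interval 0.02 to 0.65), with 7 of 15 rising and 2 falling, which handling could give, but no record of handling was used here and it cannot be told apart from time. A response to insulin at 72 h is also open and was not tested.

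At 48 h all 45 ribosomal protein and 32 of 44 oxidative phosphorylation genes rose, many of which have short transcripts, and both lists lost their calls with an estimated correlation (adjusted p = 0.415 and 0.530). Depth as the cause is argued against by the ribosomal protein medians of 48 h replicates 1 and 2, which are not the deeper library and of which the lower was 0.56. Short messenger RNAs of other pathways had a median of 0.22 at 48 h (interval 0.14 to 0.28). A length bias between libraries may therefore account for much of the oxidative phosphorylation rise. The bound was 0.13, which is 0.5 of the observed oxidative phosphorylation median, and only the share of 0.5 was set in advance. But the short list also holds mitochondrial genes, among them ROMO1, TOMM7 and MRPL36 at 0.58, 0.57 and 0.44 and MRPL33 at 0.09. A rise shared by mitochondrial genes is therefore not told apart from length. For ribosomal proteins the bound, set in the same way, was 0.28 and lay within the interval of the short messenger RNAs by a narrow margin. However, a gene span trend as the whole cause is argued against, since 40 of the 45 genes still rose with it removed (median 0.30, camera adjusted p = 2.97e-12 with the preset correlation). With no trend removed, the interval of the ribosomal protein median was 0.53 to 0.62, above that of the short messenger RNAs. No interval was computed for the median with the trend removed. The interval resamples genes, not libraries, and the medians of the 48 h libraries ranged from 0.43 to 0.71. Span includes introns and transcript lengths were not used. At 72 h against 0 h, 2 of 33 short messenger RNAs rose and 6 fell, with a median of 0.04 (interval -0.09 to 0.07). There 43 of 45 ribosomal protein genes rose, with a median of 0.37. This argues against length as the whole cause at 72 h. The comparison was not planned, and the camera call there was lost with an estimated correlation (adjusted p = 0.390). Length stays open as a part of the cause at both times and as the whole at 48 h. An effect of insulin or of time in culture also stays open and was not tested.

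Cell division genes were lower at 48 h and again at 72 h. With an estimated correlation in the camera test, only DNA replication at 72 h kept its call against 0 h (adjusted p = 0.0186). Scaling as the cause is argued against, since the highest mitosis median at 48 h under median-of-ratios scaling and equal FPKM sums was -1.15. Denser cultures over time stay open. Of 19 tested target genes of YAP and TEAD, which are less active in dense cultures, 12 fell and 3 rose at 48 h. Their median was -0.27 (interval -0.39 to -0.14), which denser cultures could give. At 72 h 10 fell and 5 rose, and the median was -0.17 (interval -0.35 to 0.13). The test asked for a median below 0 with a camera p below 0.05 at both times. The camera p was 0.00121 at 48 h (0.128 with an estimated correlation) but 0.126 at 72 h, so the test did not decide. From 48 h to 72 h, when mitosis genes fell further, 6 of these target genes rose and 1 fell. Their median was then 0.02 (camera p = 0.0452, p = 0.317 with an estimated correlation). ANKRD1, which fell at both times, and F3 had been seen to fall beforehand, so they were left out of that list and did not enter the test. An effect of insulin stays open as well, because no untreated cultures of the same age were analysed here.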

How the results depend on the processing

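The settings with equal FPKM sums, with the gene span trend removed and with only the genes that have a span were chosen only after the result was seen. Of 3334 values of the 146 gene results under other settings, 3171 kept their direction and side of the threshold, 141 lost and 3 gained the call and 19 changed sign. Of 989 values of the 43 lists past the camera test, 976 kept both and 13 lost the call. For the other 62 list results, 109 of 1417 values had the opposite sign.

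At equal FPKM sums 1959 genes were higher at 48 h and 1127 lower at 72 h than at 48 h. Library weights, whose estimation did not fully converge, gave 3823 lower genes at 48 h and 5756 genes (2408 higher, 3348 lower) for 72 h against 48 h. With only these 2 groups the fit gave 1839 (634 higher). The cause of these moves was not tested. With 1 library left out, the 72 h against 48 h counts ranged from 1727 to 3693 (589 to 1497 higher, 1138 to 2196 lower), the lowest without 48 h replicate 2 and the highest without 48 h replicate 3. The counts were 4445 to 5763 at 48 h, 4097 to 5437 at 72 h and 5547 to 7202 for the F-test. With an estimated correlation camera called 1, 2 and 1 lists at 48 h, at 72 h and for 72 h against 48 h. The directional fry test called 24, 28 and 23 and the mixed test 35, 35 and 33, and these do not compare a list with other genes.

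None of the results that changed sign had been called as reported. Library weights gave a call to HK2 at 48 h (0.38, adjusted p = 0.00303) and to IRS2 at 72 h (0.22, adjusted p = 0.0416), and leaving out 72 h replicate 2 gave one to IGFBP5 at 72 h. IRS1 at 48 h was -0.0393 rescaled to protein-coding genes, -0.0638 at equal sums and -0.00221 to 0.113 with 1 library left out. IRS2 at 48 h was -0.0127 with median-of-ratios scaling, -0.0695 rescaled to protein-coding genes, -0.0898 at equal sums, -0.000244 with the span trend removed and -0.0325 to 0.0962 with 1 library left out. HK2 at 48 h was -0.000437 at equal sums and -0.00474 to 0.291 with 1 left out, and IGFBP5 at 48 h -0.100 to 0.0481. At 72 h INSR was 0.00347 with the span trend removed, IRS1 -0.00439 at equal sums and -0.00994 to 0.117 with 1 left out, and TXNIP -0.0445 to 0.509, the lowest without 72 h replicate 2. The cause was not tested.

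The replicate numbers did not pair the libraries. Same-numbered libraries correlated at -0.071 to 0.193 in their deviations from the group means, with 2 of 9 pairs over 0.1, and 1 of 9 libraries correlated best with its own number in both other groups. With the replicate block the counts were 5632, 5152 and 3031 and no named gene or list changed its call, except for 72 h against 48 h HERPUD1 and NCL, and IDI1 and NCL with median-of-ratios scaling added. IRS2 at 48 h was -0.0127 in the block with median-of-ratios scaling. Read depth is unknown, so its limit on low genes was not measured.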

Other observations

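The lists behind the BMP, Notch and pigment cell tests were written after their leading genes had been seen and before the values of their other members were, and the genes named in this part were chosen after their values were seen. Genes that remodel the matrix moved in opposite directions. The collagenase gene MMP1 was higher at 72 h than at 0 h by 1.30 ± 0.08 on the log2 scale (SE), MMP2 by 1.16 ± 0.10, MMP14 by 1.06 ± 0.05 and PLAU, which activates plasminogen, by 0.85 ± 0.07. The inhibitor TIMP3 and the protease ADAMTS9 were lower, at -1.21 ± 0.13 and -1.11 ± 0.12. All 6 were called by limma, with adjusted p of at most 2.89e-05. The list they come from did not pass the camera test at 72 h (adjusted p = 0.263), with 8 of 17 genes rising and 6 falling. Its lowest change was -1.71, in a gene not named here.

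In the IGF system, IGFBP6 was higher by 1.57 ± 0.14 at 48 h and 0.86 ± 0.14 at 72 h, and IGFBP4 by 0.86 ± 0.07 and 0.95 ± 0.07. IGF1 itself was higher by 0.95 ± 0.21 at 72 h (adjusted p = 0.00355), and PAPPA, a protease that cleaves IGFBP4, was at -0.99 ± 0.20 at 48 h (adjusted p = 0.00244). No gene of the list was below -0.59 at 72 h. The list did not pass the camera test at 48 h or 72 h (adjusted p = 0.985 and 0.263). PLIN2, which coats lipid droplets, was lower at 72 h at -0.87 ± 0.07 (adjusted p = 2.07e-06), while 14 of 21 genes of fatty acid synthesis rose and 3 fell, a list whose call was lost with an estimated correlation (adjusted p = 0.0616). The CDK inhibitor gene CDKN2C was at -1.53 ± 0.11 at 72 h, and CDKN1C was higher.

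ID1, ATOH8 and NOG were lower at 72 h than at 48 h, and a candidate explanation is lower BMP signalling. Of 12 other BMP target genes 7 fell and 0 rose, with a median of -0.38 (bootstrap interval -0.64 to -0.25), which that hypothesis needs (camera p = 8.42e-04, but p = 0.0773 with an estimated correlation). ID3 differed by -0.98, SMAD6 by -1.02 and ID2 by -0.76.

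JAG1 and HES4 were lower at 48 h and 72 h, which might reflect lower Notch signalling. The 6 other tested Notch genes had a median of -0.41 at 72 h (interval -0.99 to 0.26), too wide to decide. Of these HEY1, HEY2 and LFNG fell, at -1.14, -0.84 and -0.55, and DLL1, a ligand, rose by 0.68. HES1 had been seen beforehand and was left out of that list. It was at 0.02 at 72 h (adjusted p = 0.914), which does not go with the hypothesis.

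GPNMB and MLANA were higher at 72 h than at 48 h. Pigment cells in the cultures are argued against, since only 1 of 9 other measured pigment cell genes, SLC45A2, reached a mean FPKM of 1 at 72 h. SLC45A2 itself was at 12.5, 14.6 and 18.5 FPKM at 0 h, 48 h and 72 h. It was called higher at 72 h than at 48 h (0.32, limma adjusted p = 0.00824), as pigment cells could give.

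The 10 splits of the 6 libraries of each comparison are too few for a share under 0.05. The real split gave 5524 genes at 48 h, 5029 at 72 h and 2814 for 72 h against 48 h, and the highest other split gave 0, 3 and 1. In each, 1 split, the real one, gave as many. For the F-test, 1 of 100 drawn splits into 3 groups of 3, the real one, gave 6704 genes and the highest other gave 473. A chance split of the libraries is argued against there. The splits cannot address a batch that coincides with time.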
